A study of Mus musculus with 6 samples.

How the data were processed

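RNA from 6 mouse colon tumours, 3 control and 3 hypomethylated, was extracted with a column kit and biotin-labelled, per the labels' protocols, and hybridised to arrays; the descriptions of some samples name the Affymetrix mouse Gene 1.0 ST type. The deposited values are taken as log2 values, 1 per probe set and array, in a single table of 28856 probe sets. In that table every probe set is centred: 100% of the rows have a median over the 6 arrays within 1e-06 of 0, so the level of a probe set is not kept. The array normalization and the summary method are not given in the sources used here. No label states the log base; base 2 was inferred from the values, and every fold printed rests on it. All values are multiples of 2 to the power of minus 20 (48.2% of probe sets) or minus 21 (51.8%), with no finer step, which is what single-precision numbers between 4 and 16 leave after centring. A probe set on the coarser step was taken to have had all 6 values at 8 or above before centring. This is an inference from the steps, and a probe set with lower values can fall on that step by chance. Values run from -6.15 to 4.26. No background signal or detection call was used, so a low group can lie at the array's floor, and a fold against it then understates the change.

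Probe sets were named through the platform annotation, with symbols updated by Entrez number to RefSeq gene names of the GRCm38.p6 assembly. Of the probe sets 21789 had 1 gene symbol, 1621 had several and 5446 had none; the first kind was used, and the others were tested apart and not named. This gave 19938 genes, of which 19856 matched by Entrez number and 82 kept the platform's symbol; no symbol changed. For the 999 genes with several probe sets the mean was taken, and 18939 had 1.

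Groups follow the genotypes in the labels. The design was written before the data were examined: limma's lmFit and eBayes without a trend, on all 6 tumours, with no block, two-sided, Benjamini-Hochberg adjusted p under 0.05 over all genes. It also planned a filter at the array's 25th percentile (50th as an alternative), the probe set with the highest mean for each gene, and a variance trend on intensity as an alternative. Centred values have no intensity, so these could not be applied: no filter was used and the mean of the probe sets was taken. A filter for genes with all values at 8 or above before centring, the restriction to genes with 1 probe set and robust eBayes without a trend were added after the data were seen. The moderation added 3.02 prior degrees of freedom. Fold changes are 2 to the power of the log2 difference of group means.

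A total of 34 gene lists with 710 entries were fixed before the data were examined, covering epithelial cell types, pathways and other cells that a tumour could hold; of their 690 genes 621 were measured, 3 of them found by an older name. Some genes are on several lists. The lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 34 lists, and also with camera at an estimated correlation and with fry. Counts of members come from the test over all genes, with the count adjusted over the list alone beside them. The rule for named genes, written before the data were examined, takes the 12 largest increases and 12 largest decreases among called genes whose groups do not overlap (predicted genes, 1 among the increases, are counted and not named), up to 4 members of each list with the smallest p, and 12 genes named in any case, of which 11 were measured; Cdkn1a has no probe set named for it alone. Members beyond these (members that went against their list, Lrig1, Saa1, most single Hox genes and the family members, 29 genes in all) were named after their values were seen. Single genes were also tested by an exact permutation test over the 20 assignments of 3 against 3, whose smallest p is 0.1.

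The scripts were tested on simulated data. For the comparison of hypomethylated with control tumours, simulated over 19938 genes, changes of 0.5, 1 and 2 on the log2 scale were recovered for 72.9%, 95.7% and 100% of the changed genes, with 12 false calls among 190. Simulated genes are independent, so this says nothing about the list tests when genes vary together. The changed genes numbered 70, 70 and 60, a far smaller share than was called in the data, and recovery depends on that share. Alternatives were the replicate number of the titles as a block, quantile normalization, centring each array on its median, array weights, other thresholds, leaving out each tumour, Spearman in place of Pearson correlation, and windows of 5 and 20 Mb around Dnmt1 in place of 10 Mb. Arrays carry no counts, so no sequencing depth applies. R 4.3.3, limma 3.58.1, Python and matplotlib were used.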

Results

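Gene expression was measured on arrays in 6 mouse colon tumours, 3 from each of 2 genotypes. All mice carried ApcMin, a truncating mutation of the tumour suppressor gene Apc that leads to intestinal tumours. The control tumours came from mice with 1 hypomorphic allele (chip) and 1 wild-type allele of Dnmt1, the gene for the enzyme that copies DNA methylation onto newly made strands. The hypomethylated tumours came from mice with the chip allele and a knockout allele (c), a genotype that the design text describes as having less methylated satellite repeats. The mice were hybrids; the parent with the c allele and ApcMin was C57BL/6 and the parent with the chip allele 129Sv4. They were given 2% (w/v) dextran sodium sulfate, a compound that injures the colon and promotes tumours, at 6 weeks of age, and tumours were taken at 20 weeks. The comparison addresses whether lower DNA methylation goes with differentiation of the tumour cells. Values are taken as log2 values, a base inferred from the values as no label states it, and are centred on each probe set's median over the 6 arrays, so they show differences between tumours and no level; 6 arrays limit the precision. The labels do not say that the tumours came from separate mice. The sample descriptions carry 1 shared number for all 3 hypomethylated tumours and another for 2 of the 3 control tumours, so p-values measure the spread between these tumours, and a difference between single mice is not separated from one between genotypes.

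Dnmt1, the altered gene, was lower in all 3 hypomethylated tumours. The control tumours had centred log2 values of 0.44, 0.52 and 0.37, and the hypomethylated tumours -0.37, -0.48 and -0.42. The group means were 0.44 ± 0.07 (SD, n = 3) and -0.43 ± 0.05 (SD, n = 3), and Dnmt1 fell by 0.87 ± 0.06 (SE) on the log2 scale, a 1.83-fold lower level (limma, adjusted p = 3.13e-04). The exact permutation test of this gene, two-sided, gave p = 0.1, the smallest that 3 against 3 allows. Where the probes lie against the altered parts of the alleles is unknown, so this value does not check the genotypes. Apc differed by -0.23 (SE 0.10, adjusted p = 0.115) and did not pass the test.

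Of 19938 genes tested, 6380 passed an adjusted p of 0.05, 2124 higher and 4256 lower in the hypomethylated tumours. Most changes were small: the median size among the called genes was 0.44 on the log2 scale, or 1.36-fold. Large changes were mostly increases, with 467 genes at least 2-fold higher against 310 at least 2-fold lower, and 126 against 27 at 4-fold. All values of one group lay above all of the other in 46.4% of all genes, where chance gives 10% on average over splits. Genes are not independent, so the share in a single split can lie far from 10% by chance. Among the called genes the share was 99.8%, which the selection by the test nearly fixes. Leaving out control replicate 1 lowered the number of called genes to 4199, 1407 higher and 2792 lower.

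The 12 largest increases were led by Cyp2c65 and Cyp2c55, cytochrome P450 enzymes, which rose by 5.20 ± 0.28 (SE) and 4.78 ± 0.62 on the log2 scale, 36.7-fold and 27.5-fold. Genes of absorptive colonocytes followed. Slc26a3, the chloride-bicarbonate exchanger of the surface epithelium, rose by 4.78 ± 0.37, the carbonic anhydrase Car4 by 4.65 ± 0.29, the fatty acid binding protein Fabp2 by 4.54 ± 0.64 and the water channel Aqp8 by 3.79 ± 0.41. Retnlb, a goblet cell product, rose by 4.06 ± 0.60 and Ido1, a tryptophan-degrading enzyme induced by interferon, by 4.04 ± 0.38. The remaining 4 were Apol10a (4.41), Mettl7b (4.07), Gsdmc2 (3.97) and Sptssb (3.87). The adjusted p-values of these 12 lay between 2.01e-04 (Cyp2c65) and 0.0134 (Gsdmc2). Cyp2c55, Cyp2c65 and Gsdmc2 have close paralogues whose transcripts their probes could share.

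The 12 largest decreases held 4 homeobox genes of the posterior body axis: Hoxd13 fell by 3.96 ± 0.12 (SE), Hoxb13 by 3.34 ± 0.56, Hoxd10 by 3.09 ± 0.24 and Hoxd11 by 3.04 ± 0.22 on the log2 scale. Dnajc6, a co-chaperone of clathrin uncoating, fell by 3.75 ± 0.15, and Smpx, a small muscle protein, fell by 3.15 ± 0.10. The transcription factors Sox17, a repressor of Wnt signalling, and Irx4 fell by 2.87 ± 0.25 and 2.82 ± 0.20. The others were Klk15 (-2.53), Ppef1 (-2.50), Gabra4 (-2.29) and Cpm (-2.29). Their adjusted p-values lay between 3.13e-05 (Hoxd13) and 0.00493 (Hoxb13).

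**Figure D1:**
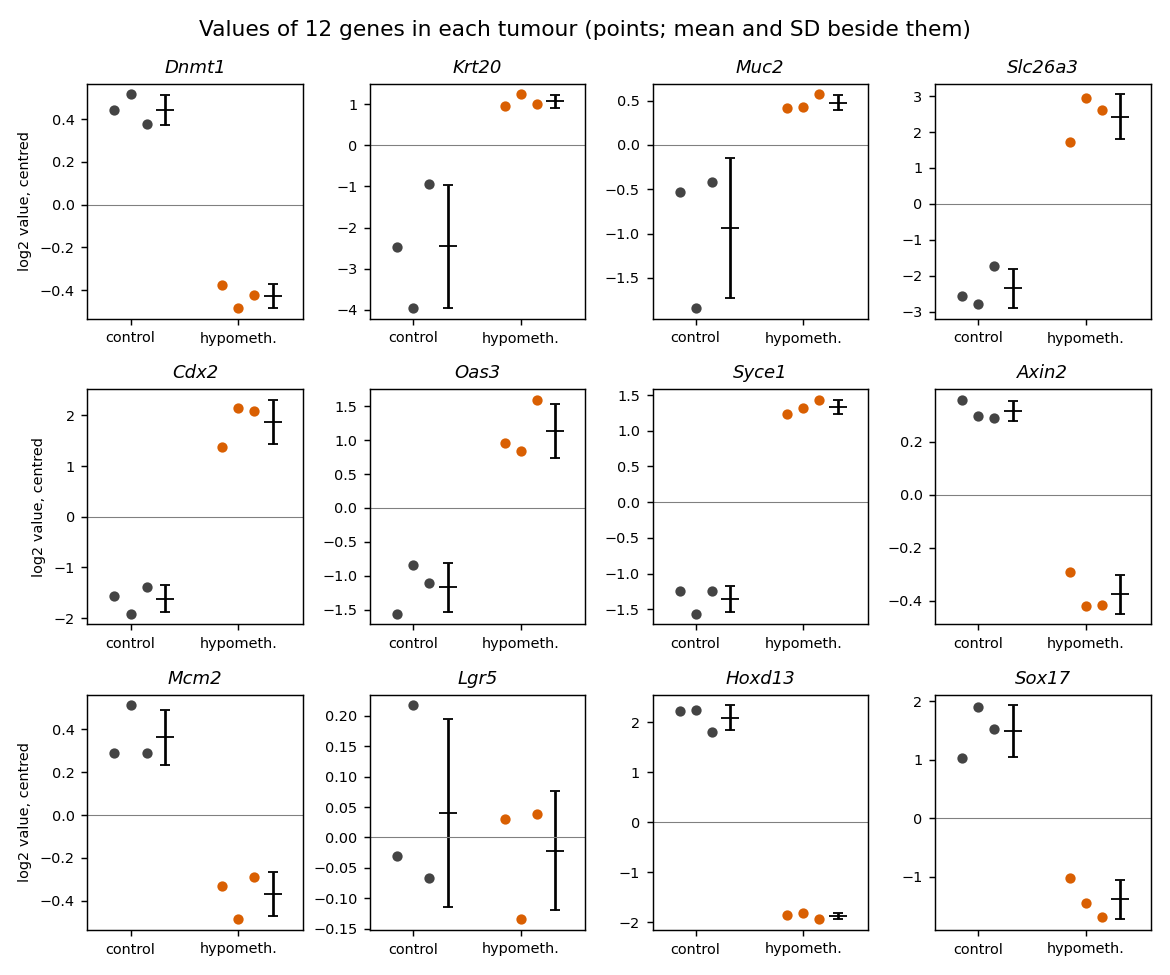
Centred log2 values of 12 genes in each of the 3 control and 3 hypomethylated tumours (points), with the group mean and SD beside them; the vertical scale differs between panels. Dnmt1, Axin2, Mcm2, Hoxd13 and Sox17 were lower and Krt20, Muc2, Slc26a3, Cdx2, Oas3 and Syce1 higher in all 3 hypomethylated tumours, while the groups overlapped for Lgr5.

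Genes of absorptive colonocytes rose as a group. Of 33 measured members 26 were higher and 2 lower (26 and 2 adjusted over the list alone), with a median difference of 2.32 on the log2 scale, 4.98-fold. Krt20, a keratin of mature surface cells, rose by 3.52 ± 0.66 (SE; adjusted p = 0.00708). The bile acid transporter subunit Slc51b rose by 3.22, and the carbonic anhydrases Car1 and Car2 by 1.80 and 1.84. Slc9a3, the sodium-proton exchanger of the same cells, and Ugt2b34 were lower, at -0.62 and -0.34. The call of Slc9a3 was lost under quantile normalization and without each tumour in turn except hypomethylated replicates 1 and 2. That of Ugt2b34 was lost with the replicate block, under quantile normalization, without control replicate 1 and without control replicate 2. The list passed camera with a preset correlation (adjusted p = 5.66e-13), with an adjusted p = 0.488 with an estimated correlation. The preset correlation takes the genes of a list as nearly independent; at that setting the 9 other splits of the 6 tumours into 3 and 3 called 8 to 18 of the 34 lists, against 19 in the real split. Each other split sets 2 tumours of a genotype and 1 of the other against the rest, so part of the genotype difference stays in it. Markers of fibroblasts, smooth muscle and endothelium, described further on with their values, were lower in the same tumours.

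Goblet cell genes also rose, 20 of 25 measured with none lower (21 higher and 1 lower adjusted over the list alone; median 1.01, 2.02-fold). They included Agr2, a disulfide isomerase needed for mucin folding (1.17), and the mucin glycosyltransferases St6galnac1 (1.73), Gcnt3 (2.42) and Galnt12 (1.54). Muc2, the main secreted mucin, rose by 1.41 ± 0.35 (SE; adjusted p = 0.0207), a call that was lost without hypomethylated replicate 2 and without hypomethylated replicate 3. Camera gave the list an adjusted p = 1.39e-09, and an adjusted p = 0.488 with an estimated correlation. Among enteroendocrine genes 8 of 22 were higher and 2 lower (9 and 2 over the list alone), 5 higher without control replicate 2. The hormone gene Gcg rose by 2.13 and the granule protein gene Chgb by 1.15, Tph1 of serotonin synthesis rose by 0.55, and Cplx2 and the peptide YY gene Pyy fell by 0.58 and 1.44. Chga rose by 0.43 (adjusted p = 0.0288). This call was lost with the replicate block, with array weights, without control replicate 2 and without each hypomethylated replicate. The enteroendocrine list had an adjusted p = 4.32e-04, and an adjusted p = 0.488 with an estimated correlation.

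Regulators of epithelial differentiation were higher in 12 of 23 measured cases and lower in 4 (12 and 5 over the list alone). Cdx2, the homeobox factor that specifies intestinal epithelium, rose by 3.49 ± 0.23 (SE), 11.2-fold, with centred values of -1.56, -1.91 and -1.38 in the control tumours and 1.38, 2.16 and 2.09 in the hypomethylated ones. The bile acid receptor Nr1h4 rose by 2.43, the vitamin D receptor Vdr by 1.76 and Pparg by 1.44. Foxa2, Bmp2, Hes1 and Ppargc1a fell by 0.78, 0.58, 0.54 and 0.97. The list's adjusted p was 0.00294, and adjusted p = 0.488 with an estimated correlation. Xenobiotic and steroid metabolism genes were higher in 13 of 22 and lower in 1 (15 and 1 over the list alone), among them Aldh1a1 of retinoic acid synthesis (3.25), Cyp3a13 (2.20) and the efflux pump Abcg2 (2.05); the lower member was Gstm1 (-0.34), whose call was lost with each array centred on its median, without control replicate 1, control replicate 3 or hypomethylated replicate 2. Fatty acid oxidation genes were higher in 9 of 18 with none lower (10 and 1 over the list alone), including Slc25a20 (1.21), Ehhadh (0.98), Acadl (0.64) and Hadha (0.40). These lists had adjusted p-values of 2.33e-07 and 8.93e-04, each with an adjusted p = 0.488 with an estimated correlation.

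Wnt target genes and cell cycle genes fell. Of 26 measured Wnt targets 17 were lower and none higher (18 lower and 1 higher over the list alone; median -0.69). The feedback regulators Znrf3, Bambi and Axin2 fell by 0.97, 1.16 and 0.69 and the transcription factor Lef1 by 1.09 (adjusted p for Axin2 = 5.40e-04). Lgr5, a stem cell receptor and Wnt target, differed by -0.06 ± 0.09 (SE; adjusted p = 0.677). Of 29 measured proliferation genes 21 were lower and none higher (23 lower over the list alone; median -0.44, 1.36-fold lower), including the replication helicase genes Mcm2 (-0.73) and Mcm5 (-0.60), E2f1 (-0.73) and the spindle checkpoint gene Bub1 (-0.84). Mki67, the gene of the Ki-67 proliferation antigen, differed by -0.20 (SE 0.10, adjusted p = 0.179) and did not pass. The Wnt list had an adjusted p = 8.50e-06, and adjusted p = 0.488 with an estimated correlation; the proliferation list had an adjusted p = 1.14e-06, and adjusted p = 0.531 with an estimated correlation. Intestinal stem cell genes did not pass as a list (adjusted p = 0.240): 3 of 22 were higher, Aqp4 (2.39), Prom1 (1.22) and Lrig1 (0.64), and 5 lower (3 and 9 over the list alone), with 10 lower with array weights. The call of Lrig1 was lost with the replicate block and without each tumour in turn except control replicate 2.

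**Figure D2:**
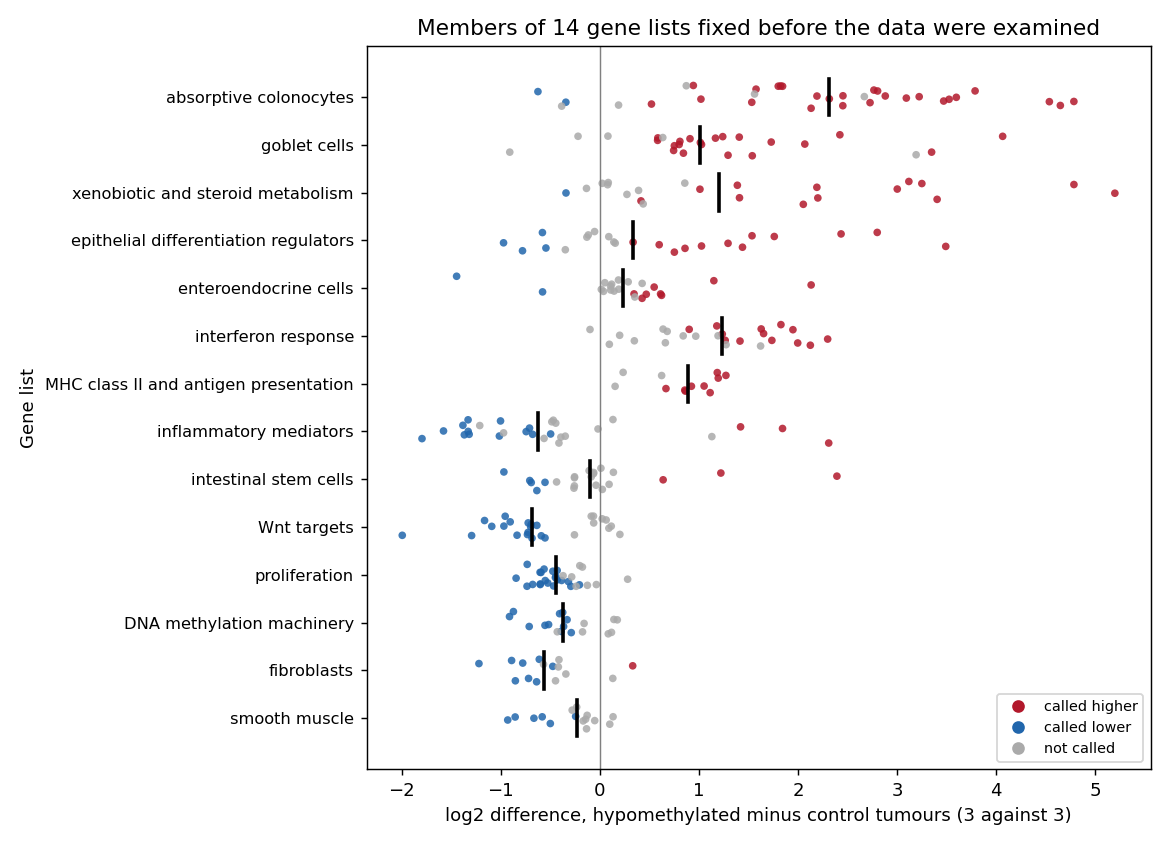
Log2 difference between hypomethylated and control tumours for each measured member of 14 gene lists (points; coloured by the test over all genes), with the list's median as a black bar. Medians range from 2.32 for absorptive colonocyte genes to -0.69 for Wnt targets.

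Genes of the methylation machinery itself were lower in 11 of 18 cases and higher in none (14 lower over the list alone; adjusted p = 0.00135, and adjusted p = 0.488 with an estimated correlation). Besides Dnmt1 they included the de novo methyltransferase genes Dnmt3a (-0.55) and Dnmt3b (-0.37), Uhrf1, which recruits DNMT1 to replicated DNA (-0.52), the dioxygenase gene Tet1 (-0.91), Gadd45b (-0.71) and Mbd3 (-0.39). The call of Dnmt3b was lost with the replicate block and without control replicate 1. Of 33 measured germline genes known to be silenced by DNA methylation 4 were higher and 1 lower (4 and 0 over the list alone); 8 were higher and 1 lower under quantile normalization, and 8 higher and 2 lower with array weights. Syce1, a component of the synaptonemal complex, rose by 2.68 ± 0.10 (SE), 6.42-fold, Tdrd1 by 1.04, Tex19.1 by 0.56 and Tex11 by 0.64, and Zcwpw1 fell by 0.23. The call of Tex11 was lost without control replicate 1, control replicate 2 or hypomethylated replicate 3. That of Zcwpw1 was lost with the replicate block and without each tumour except hypomethylated replicate 2. The list median was 0.06, its adjusted p = 0.00656, and adjusted p = 0.488 with an estimated correlation. Over all genes 2124 of 19938 were higher. Only 1 of the 33 was taken to have all values at 8 or above before centring, so the list could not be tested among such genes. Olfactory receptor genes also had a median of 0.06, so the list's small shift was not separated from one that varies with signal level. Of 27 measured imprinted genes 1, Ndn (1.22), was higher and 9 were lower (2 and 10 over the list alone), such as Plagl1 (-0.78), Mest (-0.52) and Igf2r (-0.31), and the list did not pass (adjusted p = 0.343); without hypomethylated replicate 2 and hypomethylated replicate 3 the lower members numbered 5 and 4. Of 30 measured genes known for promoter hypermethylation in colon tumours none was higher and 11 were lower (0 and 11 over the list alone), including Sox17, Esr1 (-1.15), Rarb (-1.51) and Wif1 (-0.68); this list did not pass camera (adjusted p = 0.0966) and did pass fry, as lower (adjusted p = 0.00795).

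Interferon response genes were higher in 13 of 25 cases and lower in none (16 and 0 over the list alone; median 1.24, 2.36-fold), and 21 were higher with array weights. The antiviral sensors and effectors Oas3, Oasl1 and Ifih1 rose by 2.30, 2.12 and 1.41 and the transcription factor Irf7 by 2.00. Genes of antigen presentation were higher in 9 of 12 with none lower (11 and 0 over the list alone), including the class II transactivator Ciita (1.27), Psmb9 (1.19), Tap2 (1.05) and Cd74 (0.67). Adjusted p-values were 2.33e-07 and 5.88e-06, with adjusted p = 0.523 and adjusted p = 0.488 with an estimated correlation. No member of the T and NK cell list passed in limma (0 of 16, 0 over the list alone, 1 at an unadjusted p under 0.05; list adjusted p = 0.516), and the list's median and mean differed in sign (0.02 and -0.04). Without hypomethylated replicate 1, 4 of these 16 genes were lower. Inflammatory mediators were lower in 13 of 28 and higher in 3 (15 and 4 over the list alone; adjusted p = 0.00776, and adjusted p = 0.636 with an estimated correlation); 22 were lower without hypomethylated replicate 1. The matrix metalloproteinase gene Mmp10 and the cytokine subunit gene Il23a fell by 1.58 and 1.01, whereas Duox2 and Duoxa2, which form the epithelial hydrogen peroxide generator, rose by 1.84 and 1.42 and Saa1 by 2.31. The call of Saa1 was lost with robust eBayes and without control replicate 1 or any one hypomethylated replicate, and its difference was 1.48 without control replicate 2.

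Markers of stromal cells moved with these groups. Fibroblast markers were lower in 8 of 15 and higher in 1 (12 and 1 over the list alone), with Pdgfrb, Pdgfra, Col6a3 and Fn1 at -1.22, -0.89, -0.78 and -0.47 and Fap at 0.33. Lower fibroblast members numbered 5 without control replicate 2 or control replicate 3 and 4 without hypomethylated replicate 3. Smooth muscle markers were lower in 6 of 15 with none higher (6 over the list alone), including Kcnmb1 (-0.85) and Actg2 (-0.66). Endothelial markers were lower in 8 of 14 and higher in 1, Tek (9 and 1 over the list alone), with Emcn and Cdh5 both at -0.91; leaving out control replicate 1, 2 or 3 or hypomethylated replicate 2 or 3 left 4, 2, 3, 4 and 4 lower members. Macrophage markers were lower in 4 of 15 (0 over the list alone), C1qc, Ms4a7, C1qb and Adgre1. All 4 of these calls were lost without each tumour in turn except hypomethylated replicate 1. Those of Ms4a7, C1qb and Adgre1 were also lost with the replicate block, and those of C1qb and Adgre1 with robust eBayes. That of Adgre1 was lost under quantile normalization and with each array centred on its median as well. The lower members of the list numbered 10 without hypomethylated replicate 1, 1, another gene, without control replicate 1, and 0 in the other fits without 1 tumour. The adjusted p-values of these lists were 0.00656, 0.0158, 0.0219 and 0.0451, and with an estimated correlation adjusted p = 0.536, adjusted p = 0.523, adjusted p = 0.591 and adjusted p = 0.657. The macrophage list lost its call with array weights and without control replicate 2, control replicate 3, hypomethylated replicate 2 or hypomethylated replicate 3. The pancreas or small intestine list was higher in 3 of 13 members (2 over the list alone), Apob (3.26), Rbp2 (1.73) and Apoa1 (0.27), and the adipocyte list in 3 of 9 (3 over the list alone), Cidec (1.20), Pck1 (0.62) and Retn (0.26), with 1 called without control replicate 2, hypomethylated replicate 2 or hypomethylated replicate 3. The call of Apoa1 was lost without each tumour except hypomethylated replicate 1, that of Retn without control replicates 2 and 3 and hypomethylated replicates 2 and 3, and that of Pck1 without control replicates 1 and 2 and hypomethylated replicates 2 and 3, each left out alone. The calls of Apoa1 and Retn were also lost with the replicate block. The adjusted p-values of these 2 lists were 0.0357 and 0.0356, with adjusted p = 0.523 and adjusted p = 0.488 with an estimated correlation. Both lists lost their call without control replicate 2 and without hypomethylated replicate 3.

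Position-specific homeobox genes were also counted by cluster, a grouping chosen after their values were seen. Of 12 measured genes of the posterior list 7 were lower and 2 higher (7 and 3 over the list alone), and the list as a whole did not pass camera (adjusted p = 0.101) and did pass fry, as lower (adjusted p = 0.00202). Within HoxD 5 of 9 measured genes were lower and none higher, from Hoxd8 (-0.28) and Hoxd9 (-0.51) to Hoxd13, while Hoxd12 differed by -1.35 with a 95% interval of -3.61 to 0.92, as control replicate 1 was at 3.84 and the other control tumours at 0.02 and 0.06. The call of Hoxd8 was lost with the replicate block and without control replicate 1, control replicate 3 or hypomethylated replicate 2. In HoxB 2 of 9 were lower, Hoxb13 and Hoxb9 (-0.85). In HoxA 6 of 10 were higher and none lower, with Hoxa11 at 1.07 ± 0.08 (SE) and Hoxa7 at 0.65 ± 0.08, and in HoxC none of 9 passed in limma (0 at an unadjusted p under 0.05). The proximal colon list was higher in 4 of 14 and lower in 2 (4 and 2 over the list alone). The higher members were Cyp2c55, Mettl7b, Cdx2 and Hoxa7, of which Cyp2c55 and Mettl7b are among the 12 largest increases. Nxpe4 (-1.57) and Hoxb9 were the lower ones. The list did not pass camera (adjusted p = 0.0839) and did pass fry, as higher (adjusted p = 0.0450).

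**Figure D3:**
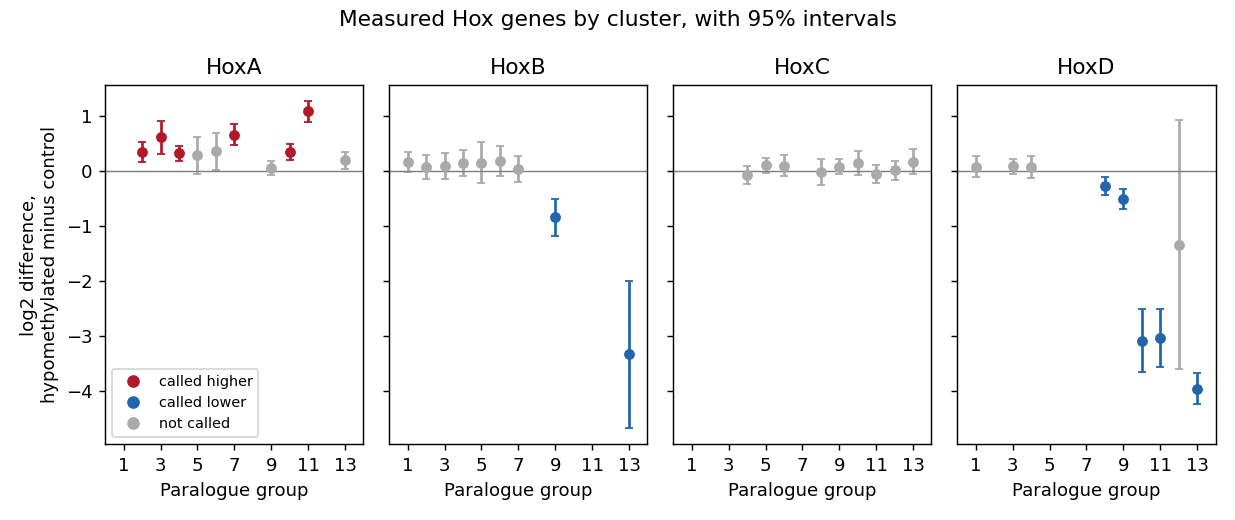
Log2 difference between hypomethylated and control tumours, with its 95% interval, for each measured Hox gene by paralogue group in the 4 clusters. In HoxD and HoxB the lower genes lie at groups 8 to 13, with Hoxd13 at -3.96, and in HoxA the called genes are higher, with Hoxa11 at 1.07.

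The remaining lists did not pass camera. Tuft cell genes had 5 members higher and 2 lower of 18 (7 and 2 over the list alone; adjusted p = 0.0921), with Hpgds and Avil at -1.81 and -1.38; 1 member was called higher without control replicate 1, control replicate 2, hypomethylated replicate 2 or hypomethylated replicate 3, and 3 without control replicate 3, whereas 9 were higher under quantile normalization and 7 with each array centred on its median. Paneth and deep crypt secretory genes had 4 higher and 2 lower of 11 (4 and 3 over the list alone; adjusted p = 0.223), with the antimicrobial lectin genes Reg3b and Reg3g at 2.84 and 1.39. Fetal-like and regenerative genes had 5 higher and 6 lower of 13 (5 and 6 over the list alone; adjusted p = 0.554), with Ly6d at 1.71 and Ccn1 at -1.27 and a median (0.14) and mean (-0.03) of opposite sign; the lower members numbered 3 without control replicate 2. Squamous epithelium genes had 2 higher and 2 lower of 15 (2 and 2 over the list alone; adjusted p = 0.770). Mast cells (0 higher, 1 lower of 10; 0 and 1 over the list alone; adjusted p = 0.108), B and plasma cells (1 higher, 0 lower of 15; 1 and 0; adjusted p = 0.240), p53 targets (1 higher, 2 lower of 17; 1 and 1; adjusted p = 0.770), enteric nerve and glia (0 higher, 1 lower of 12; 0 and 1; adjusted p = 0.770) and neutrophils (0 higher, 1 lower of 12; 0 and 0; adjusted p = 0.846) followed. Lower mast cell members numbered 4 without control replicate 2 and 5 with array weights; lower neutrophil members ranged from 0 to 3 and lower p53 targets from 0 to 4 over the fits without 1 tumour, both highest without hypomethylated replicate 1. For p53 targets the median was -0.05, positive under quantile normalization, and the test's direction was up.

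No list passed when the correlation between its genes was estimated from the 6 tumours (smallest adjusted p = 0.488, and 0 of 34 lists at an unadjusted p under 0.05), while fry, which tests whether a list's genes move on balance one way, called 17 lists. These were 14 of the 19 lists that passed camera, without the interferon response, inflammatory mediators, endothelium, adipocytes and macrophages, and 3 others. The 6 tumours separated by group: the first principal component held 78.9% of the variance. The correlation of centred values across genes averaged 0.675 within groups (0.553 to 0.795) and -0.709 between them. With no structure, values centred on their mean over 6 arrays give -0.2. The values here are centred on the median, for which that figure was not worked out. Hypomethylated replicate 1 stood apart from the other tumours of its group: its within-group correlations, 0.553 and 0.597, were the lowest of all 6, and it lay at -20.4 on the second component (8.22% of the variance), with the other tumours between -6.27 and 11.7. Without it the lower members numbered 22 against 13 for inflammatory mediators, 10 against 4 for macrophages and 4 against 0 for T and NK cells. Genes are not independent replicates, so these correlations carry no p-value.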

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

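The probe sets without a single gene symbol, which the comparisons of genes left out, also differed between the groups. Of 7067 such probe sets 693 were higher in the hypomethylated tumours than in the control tumours and 440 were lower, in the same limma fit over all probe sets. Over all 28856 probe sets 2866 were higher and 4808 lower. The share of increases was thus about the same in both sets, and the share of decreases was smaller among the 7067. The largest increase was 3.72 on the log2 scale, for probe set 10428960, which the platform assigns to several genes; its centred values were -2.10, -4.03 and -0.54 in the control tumours and 0.54, 1.99 and 1.96 in the hypomethylated tumours (adjusted p = 0.0208). The largest decrease, of probe set 10566258, was -2.23. No group has 4 or more samples, so no test for a single outlying tumour was made.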

How the results depend on the processing

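The filter to genes with all values at 8 or above before centring, the restriction to genes with 1 probe set and robust eBayes were chosen after the data were seen. Not run, as centred values have no level: the percentile filters, the highest-mean probe set and both intensity trends. No called gene changed direction under any setting that refitted it. The share of lower calls was 66.7%, 56.9% under quantile normalization, 61.8% with each array centred on its median and 69.7% under the filter at 8, where the median gene differed by -0.11. The titles number the tumours 1 to 3 in each group. Deviations from the group mean correlated at -0.29, -0.31 and -0.22 between tumours of one number, and at 0.05 to 0.29 between tumours of different numbers. The deviations in a group sum to 0, which binds these correlations together, so they do not settle whether the numbers pair tumours. With the number as a replicate block 4257 genes were called, 1543 higher and 2714 lower, 4225 of them among the 6380. Leaving out each tumour gave 4199 to 6593 called genes, 1407 to 2323 higher and 2792 to 4270 lower; the lowest count came without control replicate 1. A 2-fold minimum left 777 genes, 467 higher and 310 lower. Without each tumour in turn 16 to 22 lists were called, against 19: the macrophage list lost its call without control replicates 2 and 3 and hypomethylated replicates 2 and 3, each left out alone, and with array weights, and the adipocyte and the pancreas or small intestine lists without control replicate 2 and hypomethylated replicate 3. Calls were gained by the hypermethylated and proximal colon lists without control replicate 1 and without hypomethylated replicate 1, by mast cells without control replicate 2, by tuft cells without hypomethylated replicate 1, by the posterior Hox list with 1 probe set per gene and by the proximal colon list with the replicate block. The filter at 8 called 12 lists; enteroendocrine cells, inflammatory mediators, smooth muscle, endothelium and macrophages lost their call there, Paneth cells gained one, and some lists had too few genes to test. With an estimated correlation 0 lists were called: the adjusted p was 0.488 for absorptive colonocytes, goblet cells and Wnt targets, 0.531 for proliferation and 0.523 for the interferon response; fry gave 0.0599 for the interferon response. The mean within-group correlation was 0.675 by Pearson and 0.547 by Spearman. Of the 137 named genes that passed, 118 did so in every setting that tested them and 19 lost the call in at least 1; 13 named genes that had not passed did so in some setting. Of the 27 called genes among the 29 named after their values were seen, 7 lost the call in at least 1 setting. Beyond fewer samples in the leave-one-out fits, and fewer genes under the filter, the cause was not tested. What share of the low values lie at background is unknown.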

Other observations

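The tests of tissue dilution, Hox position and the chromosomal neighbourhood, the count of genes over other splits, and the gene families below were chosen or had their bounds written only after the result was seen; the comparison of windows around Dnmt1 itself was planned.

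Families of genes that share the letters of their symbol were counted. Cytochrome c oxidase genes (Cox) were higher in 14 of 25 cases and lower in none, such as Cox6a1 (0.59) and Cox7a2 (0.32), and Myo genes, unconventional myosins, in 10 of 24 with none lower, with Myo1a at 1.58 and Myo6 at 0.94. Carbonic anhydrases, some of them also on the absorptive colonocyte list, were higher in 7 of 16, among them Car12 (2.74), Car13 (2.13) and Car9 (2.11). Nuclear pore genes (Nup) were lower in 16 of 20 and higher in none, such as Nup188 (-0.62), Mediator subunits (Med) in 14 of 30, with Med18 at -0.83, intraflagellar transport genes (Ift) in 9 of 14, with Ift80 at -0.77, histone deacetylases in 8 of 11, with Hdac6 at -0.73, and CCR4-NOT subunits (Cnot) in 8 of 11. Zinc finger genes with Zfp symbols were lower in 140 of 347 and higher in 9. These directions held under quantile normalization and with each array centred on its median. Of 323 families 64 passed camera at the preset correlation, but those given here had an adjusted p = 0.847 with an estimated correlation, and splits of the 6 tumours other than the real one called up to 73 families.

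Olfactory receptor genes, 1027 in number, differed by a median of 0.06, with 29 higher and 1 lower. Under quantile normalization 107 were higher and 1 lower. The Vmn, Krtap and Mir families also had medians above 0, at 0.05, 0.13 and 0.04 (4, 5 and 19 members higher, 0, 0 and 7 lower). Genes taken to have all values at 8 or above before centring had a median of -0.11. Small differences, as most called genes and the Nup, Med, Cnot, Ift and Zfp families showed, were therefore not separated from a shift that varies with signal level. The same holds for the median of the germline gene list, 0.06.

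The rise of absorptive colonocyte and goblet cell genes may reflect more untransformed mucosa in the hypomethylated pieces of tissue rather than a change in the tumour cells. If tissue mixture set these genes, their order of difference between 2 control tumours would resemble their order between the groups. This holds only if those 2 control tumours differ mainly in their share of mucosa, which is not known. Without that, a rho near 0 does not speak against mixture. Over 58 genes, Spearman's rho between control 1 minus control 2 and the hypomethylated mean minus control 3 was -0.0438 (bootstrap 95% interval -0.309 to 0.231; across genes, which are not independent replicates), an interval that holds 0, so mixture and a change in the tumour cells cannot be told apart here. Dilution of tumour RNA by up to an equal amount of other tissue lowers no gene by more than 2-fold; limma's treat over all genes, which took the place of an earlier count of intervals among genes already called lower, put 33 genes lower by more than 2-fold (adjusted p under 0.05), so dilution of that size does not account for the deepest falls, which would need 93.6% other tissue for Hoxd13. The genotype, which the design names, was not tested apart from these or from a difference between single mice. Nor was it tested apart from the tumours' position in the colon, taken up next.

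The fall of HoxD genes and Hoxb13 may come from hypomethylated tumours having lain in a more proximal part of the colon, since these genes mark the distal gut; the labels give no position. Were position the cause, the HoxA genes of paralogue groups 10 to 13 might be expected to fall with them. None was lower, and 2 of the 3 measured were called higher, Hoxa10 (0.33) and Hoxa11 (1.07), with Hoxa13 at 0.19 and not called. Hoxa13 was called higher under quantile normalization (0.25), with each array centred on its median (0.21) and under the filter at 8 (0.19), so all 3 were called higher there. The call of Hoxa13 thus depends on the setting, and no table gives these genes' levels along the colon, so position and the genotype cannot be told apart. The preset proximal colon list also holds Cyp2c55, Mettl7b, Cdx2 and Hoxa7, which rose, and Nxpe4 and Hoxb9, which fell. For these genes, too, position was not separated from the genotype.

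The c allele may carry flanking DNA of another strain, which would place changed genes near Dnmt1 on chromosome 9. Of 163 genes within 10 Mb of it 38 were called (23.3%), against 32.2% elsewhere, and the share was 18.5% within 5 Mb and 21.4% within 20 Mb. Without olfactory receptor genes, of which 36 lie within 10 Mb, it was 28.3% against 33.7%. The share near Dnmt1 was thus not raised. The genes there are too few to make up most of the 6380 calls whatever their share, so this count could not test flanking DNA as a main source. It also does not test single neighbours or effects of flanking DNA on genes elsewhere.

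The count of 6380 genes was reached by 1 of the 10 splits of the 6 tumours into 3 and 3, the real one, and the highest of the other splits called 0 genes in limma, with up to 889 at an unadjusted p under 0.05. The count of 19 lists was also reached by 1 of 10 splits, and the other 9 called 8 to 18 lists at the preset correlation. Each of the 9 other splits keeps part of the genotype difference, with 2 tumours of a genotype on one side and 1 on the other. The rest of that difference becomes spread within each side and widens the errors in limma. A count of 0 genes there is thus no measure of what chance alone would call. The 10 splits are too few for a share under 0.05.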
